A study of Homo sapiens with 4 samples.

How the data were processed

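RNA was sequenced from HEK293 cells, an established human embryonic kidney line, in 4 libraries, with 1 library in each of 4 groups. Per the labels, 3 groups came from cells grown with 4-thiouridine (4SU) and 6-thioguanosine (6SG), each at 200 µM. These are photoreactive analogues of uridine and guanosine that cells build into new RNA. The groups were poly(A) RNA of unlabelled cells, oligo(dT)-purified RNA of labelled cells without irradiation, the part of that RNA recovered on streptavidin after its thiol groups had been biotinylated, and oligo(dT)-purified RNA of labelled cells irradiated at 365 nm. Light of this wavelength crosslinks the analogues to bound protein. Per the series' design text, the labelled precipitates came from repeated rounds of oligo(dT) purification and their cDNA was made by random priming. Strand information is not given in the sources used here.

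The deposited table holds FPKM values (fragments scaled by transcript length and by the number of mapped fragments), made by the authors with Cufflinks 1.03 on genome build hg18, per the submitters' processing notes. The aligner and the read totals are not given in the sources used here. The table has 37398 entries by Ensembl gene ID, with a single status for all libraries. The 491 entries whose status was FAIL were left out, 250 of them protein-coding, which left 36907. All per-library columns of the table were used. A locus in the table is a bundle that can span several neighbouring or overlapping genes, and coordinates are given as in the table, on hg18.

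The reference annotation used here, GENCODE v29, is on another genome build, so none of its coordinates were used. It supplied gene types (24615 of the 37398 IDs) and the length and GC content of each gene's longest protein-coding transcript (17651 of 17668 nuclear protein-coding genes, 99.9%). Current symbols came from a name table that held 24573 of the IDs.

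Depth was looked for in the low values. For genes with a single protein-coding transcript, FPKM times length was binned in steps of 0.2 on the log2 scale. The pair of bins with most genes held 3.24 times as many genes as the bins just below it in the unlabelled library and 5.18 times in the labelled non-irradiated one, against 1.38 in the biotin-purified and 1.32 in the irradiated library. Only a ratio of at least 2, a limit set after these histograms had been seen, was read as the step of 1 fragment. It put the unlabelled library at about 23.7 M and the labelled non-irradiated one at about 11.8 M fragments (M, mega), which are rough estimates because the lengths come from another annotation. The depth of the other libraries is unknown. At 5 FPKM a transcript of 3 kb would then have about 355 fragments in the unlabelled and 178 in the labelled non-irradiated library. Whole read counts were not recovered, and no count model was used.

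For each comparison, the log2 ratio of FPKM plus a pseudocount of 1 was taken per entry, over entries whose mean FPKM in the libraries compared was at least 1. Fold changes are on this scale, which understates differences of low genes. With 1 library per group there is no replicate check, no test and no p-value, and each statement compares these libraries, not the conditions. Because the FPKM of a library share a common total, ratios are also given relative to the median gene. This does not remove a common factor fully, because the pseudocount shrinks ratios of low genes more than those of high ones. Percentiles are less open to this, since the random lists are matched on expression.

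Before the data were examined, 25 gene lists with 1013 names were fixed. Of these names, 919 matched a single entry, 6 matched several and were left out, and 88 matched none, MALAT1 and NEAT1 among them. A list with at least 5 measured members was described by its median log2 ratio and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. A list is said to stand apart when its median lay outside the central 95% of its random lists. Some lists stand apart by chance at that limit. In simulated lists of 40 genes placed in the 14449 entries of the irradiation comparison, 7.5% of 40 lists stood apart with no planted shift. With a shift of 0.5 on the log2 scale 62.5% did, and with a shift of 1 100% did. Simulated values were independent between genes and members were picked at random. Real lists can share length or GC content, to which ratios were related, so more of them may stand apart without a shift.

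The genes named were fixed by a rule written before the data were examined, namely the 10 highest and 10 lowest ratios per comparison at a mean FPKM of at least 5, the 2 highest and 2 lowest members of each list at that level, and ACTB, GAPDH, MALAT1, NEAT1, MYC and EEF1A1. The top of these rankings held mostly ribosomal and small RNAs and unnamed entries. A ranking of nuclear protein-coding genes alone was therefore added after the values had been seen, and the genes named from it are marked as such. Members whose ID and name in the table point to different genes were not named.

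The alternatives planned were pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, centring on the median, rescaling to a common sum without mitochondrial, ribosomal RNA and small RNA entries (35 mitochondrial entries and 4640 others), and other reference libraries. This rescaling kept IDs absent from the reference annotation unless their names marked them as rRNA or small RNA. Rescaling over nuclear protein-coding genes, random lists matched also on length or on length and GC content (5 bins each), and the biotin-purified library as the labelled library were added after the data had been seen. By gene ID only 26 of 49 histone genes had a length in the labelling comparison, under the 80% asked for, so lengths of 481 entries with retired IDs were paired by gene name for that list, after its values by ID had been seen. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.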

Results

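Gene expression was measured by RNA sequencing in 4 HEK293 libraries, with no replicates. The summed FPKM was 659518 in the unlabelled library, 1638350 in the labelled non-irradiated library, 1015996 in the biotin-purified library and 2993355 in the labelled irradiated library. Nuclear protein-coding genes held 61.0% of the sum in the unlabelled library, 13.2% in the labelled non-irradiated, 29.3% in the biotin-purified and 2.90% in the irradiated library. Named cytosolic ribosomal RNA (rRNA) entries held 0.291%, 12.1%, 3.01% and 13.6%, in the same order. Of these 441 entries, 414 were named as 5S, 5 as 5.8S and 22 as small-subunit rRNA. None was named for the long rRNA of the large subunit, so these percents are not the whole rRNA share. Small-subunit entries alone held 0.279%, 11.8%, 2.73% and 13.3%. Entries whose ID is not in the reference annotation and which are not named as rRNA held 19.2%, 65.7%, 38.9% and 80.6%. The 20 highest entries of each library held 14.9%, 62.5%, 37.8% and 79.8% of its sum. Over 11042 nuclear protein-coding genes the median FPKM was 11.0 in the unlabelled, 7.48 in the labelled non-irradiated, 8.12 in the biotin-purified and 0.810 in the irradiated library, so values for most mRNAs were lowest in the irradiated library.

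**Figure D1:**
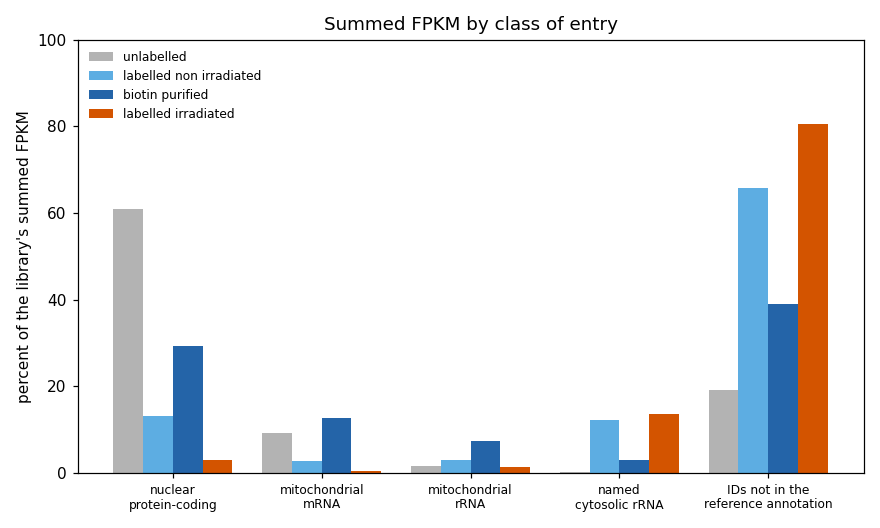
Bars give the percent of each library's summed FPKM held by 5 classes of entry, with 1 bar per library and no error because each group is 1 library. Nuclear protein-coding genes go from 61.0% of the sum in the unlabelled library to 2.90% in the irradiated library.

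Agreement between libraries was measured across nuclear protein-coding genes, which are not independent replicates. The labelled non-irradiated and biotin-purified libraries were closest, with Pearson's r of 0.93 and Spearman's rho of 0.93 on log2(FPKM + 1) across 11072 genes, a median absolute log2 ratio of 0.41 and 88.0% of genes within 2-fold. The unlabelled library had r of 0.83 (rho 0.80) with the labelled non-irradiated, 0.87 (rho 0.84) with the biotin-purified and 0.83 (rho 0.80) with the irradiated library. The irradiated library had r of 0.81 (rho 0.77) with the non-irradiated and 0.80 (rho 0.79) with the biotin-purified library. Over all entries, 57.0% lay within 2-fold between the unlabelled and labelled non-irradiated libraries, 67.3% between the unlabelled and biotin-purified, 80.7% between the labelled non-irradiated and biotin-purified, 13.8% between the non-irradiated and irradiated, 10.5% between the biotin-purified and irradiated and 6.41% between the unlabelled and irradiated libraries. After centring on the median these were 66.0%, 70.7%, 82.3%, 73.1%, 69.1% and 69.6%, in the same order.

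The labelled non-irradiated library was compared with the unlabelled one to ask how the poly(A) transcriptome of labelled cells differed. Messenger RNAs of KRAB zinc finger genes, which encode DNA-binding repressors, and of replication-dependent histones, most of which end in a stem-loop and not in a poly(A) tail, were higher in the labelled library. Small RNAs without a poly(A) tail were higher too. Genes of the unfolded protein and integrated stress responses were lower than the median gene. Those of the proteasome, of oxidative phosphorylation and of glycolysis were lower too, but did not stand apart with the purified library as the labelled one (percentiles 24.9, 8.33 and 3.23). Of the 111 KRAB zinc finger genes measured, 61 lay at least 2-fold above the median gene and 4 at least 2-fold below, and the list median was 2.21-fold above it (log2 1.14, percentile 100 of its random lists). ZNF460 was listed at 2.68 FPKM in the unlabelled and 36.0 in the labelled library, and ZNF551 at 4.67 and 35.2, whereas ZNF777 was at 21.3 and 3.49. Of 49 histone genes, 41 lay at least 2-fold above the median gene and none at least 2-fold below (list median 3.42-fold above, percentile 100). H4C3 (HIST1H4C), a histone H4 gene in the locus at chromosome 6, 26129884 to 26314243, went from 0.772 to 80.5 FPKM. Near-identical histone copies share reads, so single members are uncertain. Of 19 small RNAs 16 lay at least 2-fold above (list median 5.91-fold above, percentile 100), with SCARNA13 at 2.80 and 80.0 FPKM and SNORD17 at 3.89 and 80.2.

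Among all entries, the highest ratios in this comparison belonged to rRNA and 7SK entries, which are structural or regulatory RNAs. A small-RNA entry for 5.8S rRNA on chromosome 2 (RNA5-8SP5, 132727196 to 132727348) was at 3.50 FPKM in the unlabelled and 2941 in the labelled library, and 7SK on chromosome 6 (52968376 to 52968707) at 8.80 and 1520. From the ranking of protein-coding genes added after the values were seen, KRBA2 was at 0.783 and 43.4 FPKM, IFI35 at 0.775 and 18.8, ZNF121 at 4.85 and 58.6, and UHMK1 at 4.12 and 44.2. EGR1, an immediate early transcription factor, was at 10.1 and 80.0 FPKM. Among the lowest were C7orf50 at 38.6 and 0.989 FPKM, GDF15, a stress-induced secreted factor, at 104.5 and 5.56, PSMA6, a subunit of the proteasome core, at 72.4 and 3.62, PKIG at 23.1 and 0.516, and CDC42EP1 at 69.0 and 4.09. HES1, a Notch target, was at 172.4 and 17.8.

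The lists that lay lower in the labelled non-irradiated library were, first, glycolysis (17 genes, 1.91-fold below the median gene, percentile 0.505) and proteasome (31 genes, 1.88-fold below, 0.15). Nuclear-encoded oxidative phosphorylation (75 genes, 1.81-fold below, 0.01) and stress responses (26 genes, 1.71-fold below, log2 -0.41 from its random lists) were lower too. Mitochondrial ribosomal proteins (69 genes, 1.56-fold below, 1.25) were also lower, but that call ended or changed sign in 4 of 9 alternatives. The others were secreted and membrane glycoproteins (39 genes, 1.54-fold below, 0.55, but 3.89 with a pseudocount of 5) and interferon-stimulated genes (20 genes, 1.35-fold below, 2.26). Interferon-stimulated genes no longer stood apart in 6 of 9 alternatives. ENO1, a glycolytic enzyme, was at 2011 FPKM in the unlabelled and 513 in the labelled library, COX5A, a subunit of cytochrome c oxidase, at 219 and 36.5, and PHGDH, of serine synthesis, at 466 and 53.9. Genes for hnRNP and SR splicing factors lay 1.12-fold below the median gene but above 99.2% of their random lists, so the sign against all genes and against matched lists differs. Mitochondrially encoded mRNAs were 1.20-fold above the median gene (10 genes, percentile 98.4), but did not stand apart with a mean FPKM of at least 5 (97.1). No list of cell cycle, heat shock, p53 target, translation factor, immediate early, cytosolic ribosomal protein, long non-coding RNA or sterol genes stood apart. ACTB was at 511 and 293 FPKM, GAPDH at 1251 and 469, MYC at 39.2 and 10.7 and EEF1A1 at 1508 and 1243.

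Over 16958 entries the median log2 ratio was -0.51, and 2171 entries were at least 2-fold higher and 5122 at least 2-fold lower in the labelled library. After centring on the median the split turned to 3497 higher and 2268 lower, and rescaling gave from 638 higher and 11493 lower (without mitochondrial, rRNA and small RNA entries) to 3274 higher and 1504 lower (over protein-coding genes). The former kept IDs absent from the reference annotation unless named as rRNA or small RNA. Such IDs not named as rRNA held 19.2% of the unlabelled and 65.7% of the labelled sum, so their effect on the split was not removed. In nuclear protein-coding genes the median was -0.62 (11623 genes). Ratios were related to transcript length (Spearman's rho 0.42 across 7911 genes) and to GC content (rho -0.34). With random lists matched on length, mitochondrial ribosomal protein (percentile 63.0), splicing factor (88.1), interferon-stimulated (23.4) and oxidative phosphorylation genes (3.16) no longer stood apart, while cytosolic ribosomal protein (99.7) and sterol genes (99.3) did. With GC content matched as well, oxidative phosphorylation stood apart (0.65), and mitochondrial ribosomal protein (56.7), splicing factor (63.5), interferon-stimulated (14.4) and glycolysis genes (5.28) did not. With the purified library as the labelled one, mitochondrial ribosomal protein genes lay above their random lists (99.99), and interferon-stimulated (7.95) and splicing factor genes (21.1) within them.

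The irradiated library was compared with the labelled non-irradiated one to ask which transcripts differed after irradiation at 365 nm. Messenger RNAs of cytosolic ribosomal proteins and oxidative phosphorylation subunits lay above the median gene in the irradiated library, while those of hnRNP and SR splicing factors lay below it. Of 73 ribosomal protein genes, 65 lay at least 2-fold above the median gene and none at least 2-fold below (list median 3.79-fold above, percentile 97.7). RPL9 was at 320 FPKM without irradiation and 694 with it and RPS3A at 308 and 729. RPS3A has many near-identical pseudogene copies, so its value is uncertain. The random lists matched to ribosomal protein genes had a median log2 of 1.55 against 1.92 for the list. They were drawn from all kinds of entries of like FPKM, ribosomal protein genes included, so they do not stand for highly expressed mRNAs as such. Matching on both libraries also favours entries that are high after irradiation. With entries of mean FPKM of at least 5 alone, the list lay -0.0096 from its random lists on the log2 scale. Of 32 hnRNP and SR genes, 18 lay at least 2-fold below the median gene and none at least 2-fold above (list median 2.09-fold below, percentile 0). HNRNPAB was at 117.5 FPKM without irradiation and 4.46 with it, and SRSF4 at 54.4 and 1.95. With random lists matched on length as well, this list lay at percentile 9.07, and with GC content too at 5.31.

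Of 75 oxidative phosphorylation genes 27 lay at least 2-fold above the median gene (list median 1.76-fold above, percentile 99.8), with NDUFB11 at 67.4 and 74.8 FPKM and CYCS, which carries electrons to complex IV, at 59.7 and 6.23. The other lists above their random lists were histones (48 genes, 1.72-fold above the median gene, percentile 100), a list of small RNAs (19 genes, 2.95-fold above, 100, unlike the U6, Y RNA and 5S rRNA entries given below), interferon-stimulated genes (19 genes, 1.36-fold above, 99.3) and secreted and membrane glycoproteins (35 genes, 1.14-fold above, 98.4). The call on the last ended or changed sign in 5 of 9 alternatives and that on interferon-stimulated genes in 4 of 8. Mitochondrial ribosomal protein genes were 1.19-fold below the median gene but at percentile 98.1, a call that ended or changed sign in 4 of 9. KRAB zinc finger genes were 1.45-fold below (108 genes, percentile 0.01) and mitochondrially encoded mRNAs 1.31-fold below (10 genes, percentile 0.4). ZNF227 was at 74.7 and 3.09 FPKM and MT-ND5 at 2249 and 192. The KRAB list no longer stood apart with a pseudocount of 0.1 (percentile 2.74), nor the mitochondrially encoded one without a filter (4.24). With the unlabelled library as reference the KRAB list lay 1.55-fold above the median gene (percentile 100), which turns its direction, and oxidative phosphorylation (percentile 56.7), mitochondrially encoded (6.78), mitochondrial ribosomal protein (10.6), interferon-stimulated (48.3) and glycoprotein genes (30.5) no longer stood apart.

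WDR6, encoded on chromosome 3 (49019695 to 49035926), had the lowest ratio of any protein-coding gene, at 63.1 FPKM in the non-irradiated and 0.367 in the irradiated library. From the protein-coding ranking added later, SRRM2, a nuclear splicing coactivator, was at 226 and 7.22 FPKM, CNP at 41.5 and 0.583, CLK2, a kinase of SR proteins, at 63.4 and 1.82, and MSH6, of DNA mismatch repair, at 30.7 and 0.444. At the other end, RPLP0 was at 1194 and 2520 FPKM, RPL27 at 1121 and 2264, RPS15A at 758 and 1352 and EIF3E at 57.2 and 98.3. Several U6 and Y RNA entries among the lowest of all entries were listed at 0 in the irradiated library. Summed FPKM was 28.9 times lower there for U6, 70.3 times for Y RNA and 52.2 times for 5S rRNA entries, against 2.49 times for nuclear protein-coding genes. Without irradiation these classes summed to only 620, 745 and 206 FPKM over 967, 777 and 414 entries, so their mean entry was low. SRP RNA entries were 3.60 times lower too, but 7SK, U2 and 5.8S rRNA entries were 1.27, 2.20 and 1.65 times higher. ACTB was at 293 and 71.2 FPKM, GAPDH at 469 and 448, MYC at 10.7 and 1.68 and EEF1A1 at 1243 and 1751. Relative to the median gene, ACTB had a log2 ratio of -0.04 and EEF1A1 of 2.48. Immediate early, glycolysis, p53 target, stress response, heat shock, cell cycle, proteasome, translation factor and sterol genes did not stand apart, although with length-matched random lists translation factor (percentile 100) and glycolysis genes (99.6) did.

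Over 14449 entries the median log2 ratio of irradiated over non-irradiated was -1.98, and 143 entries were at least 2-fold higher and 12315 at least 2-fold lower. After centring the split was 2099 higher and 1788 lower, and with rescaling over protein-coding genes 293 higher and 9382 lower. In nuclear protein-coding genes the median was -2.12 (10032 genes). Named cytosolic rRNA entries summed to 2.05 times as much FPKM in the irradiated library, and all entries together to 1.83 times as much.

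The biotin-purified library was compared with the labelled non-irradiated one, the precipitate it came from, to monitor by gene how far the nucleosides had been incorporated. Mitochondrial ribosomal protein, proteasome and mitochondrially encoded mRNAs were higher in the purified library, and small RNAs without a poly(A) tail were lower. With the unlabelled library as reference, however, proteasome genes did not stand apart (percentile 25.4). Small RNAs then lay 3.66-fold above the median gene (percentile 100). Of 69 mitochondrial ribosomal protein genes, 42 lay at least 2-fold above the median gene and none at least 2-fold below (list median 2.12-fold above, percentile 100). MRPL43 was at 8.02 FPKM before and 87.0 after purification. Of 31 proteasome genes, 15 lay at least 2-fold above (list median 1.99-fold above, percentile 99.9), led by PSMA6 at 3.62 and 51.1 and PSMA2 at 44.2 and 126.7. PSMA6 was higher still in the unlabelled library, so its ratio rests on the low value in the non-irradiated one. Of 10 mitochondrially encoded mRNAs, 8 lay at least 2-fold above (list median 2.30-fold above, percentile 99.4), with MT-CO2 at 4140 and 18372 FPKM.

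Histone genes (54 genes, 1.74-fold above the median gene, percentile 100), oxidative phosphorylation (75 genes, 1.70-fold above, 99.4) and immediate early and short-lived mRNAs (47 genes, 1.32-fold above, 98.5) were also higher. The call ended or changed sign in 1 of 10 alternatives for histone genes and in 4 of 10 for oxidative phosphorylation. Immediate early mRNAs no longer stood apart in 7 of 10. Within the immediate early and short-lived list, ID3 was at 5.52 and 16.8 FPKM and MCL1 at 61.7 and 39.9. Cytosolic ribosomal protein genes had a median ratio close to that of the median gene but lay below all of their random lists (73 genes, percentile 0), with RPS21 at 1063 and 376 and RPL14 at 142 and 391. Splicing factor genes lay 1.08-fold above the median gene and at percentile 0.39. Secreted and membrane glycoproteins were 1.17-fold below (37 genes, percentile 0.46), with PTPRF, a receptor phosphatase, at 17.7 and 6.82. Small RNAs were 1.68-fold below (18 genes, percentile 0.01), with SNORD17 at 80.2 and 10.5, and named cytosolic rRNA entries summed to 6.48 times less FPKM in the purified library. From the protein-coding ranking added later, ANAPC13 was at 6.01 and 56.2 FPKM, RANGRF at 2.76 and 23.4 and POLR1D at 55.0 and 228, while ACSBG2 was at 13.7 and 0.183 and BNIPL at 16.6 and 2.94. ACTB was at 293 and 589, GAPDH at 469 and 975, MYC at 10.7 and 22.7 and EEF1A1 at 1243 and 914. KRAB zinc finger, glycolysis, p53 target, stress response, heat shock, interferon-stimulated, cell cycle, translation factor and sterol genes did not stand apart.

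Over 16418 entries the median log2 ratio was 0.13, with 2014 entries at least 2-fold higher and 1151 at least 2-fold lower in the purified library, and 1495 higher and 1412 lower after centring. The split depends on scaling, with 6587 higher and 290 lower when rescaled without mitochondrial, rRNA and small RNA entries and 329 higher and 1941 lower when rescaled over protein-coding genes. The former kept IDs absent from the reference annotation unless named as rRNA or small RNA. Such IDs not named as rRNA held 65.7% of the non-irradiated and 38.9% of the purified sum. Ratios were related to transcript length (rho -0.58 across 7157 genes). With random lists matched on length, oxidative phosphorylation (percentile 80.2), glycoprotein (7.29), splicing factor (3.15) and immediate early genes no longer stood apart. With GC content matched too, splicing factor genes did (2.26). With the unlabelled library as reference, proteasome (percentile 25.4), oxidative phosphorylation (8.46), immediate early (80.1) and splicing factor genes (22.1) no longer stood apart, small RNAs were higher (1.87 above the median gene on the log2 scale), and the mitochondrial ribosomal protein (percentile 99.96), mitochondrially encoded (99.5) and histone (100) lists stayed above their random lists. With the irradiated library as reference, histone (-0.47 from their random lists on the log2 scale) and oxidative phosphorylation genes (-0.64) lay below and splicing factor genes (0.73) above them, which turns their direction, and proteasome genes did not stand apart (percentile 74.2).

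**Figure D2:**
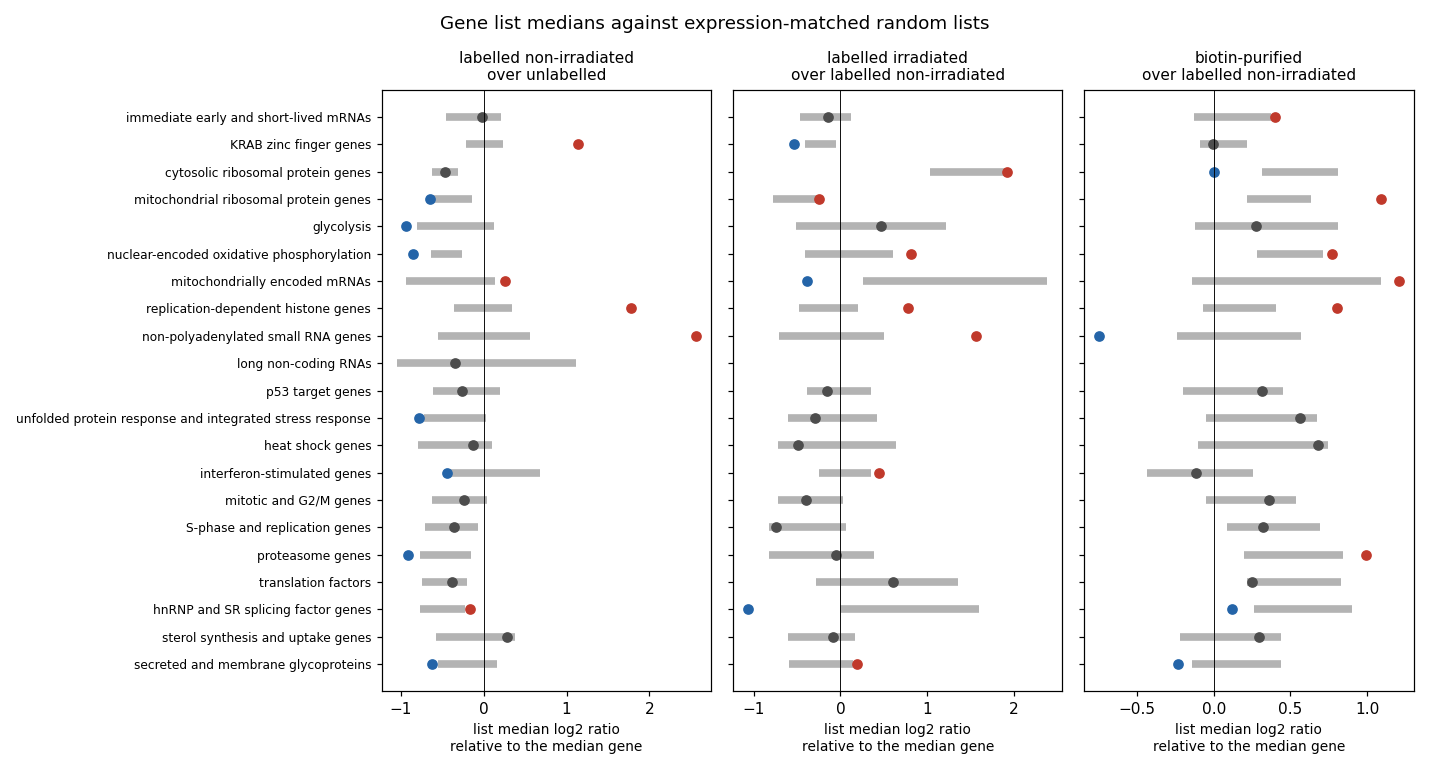
Each point is the median log2 ratio of a gene list relative to the median gene in 1 of 3 comparisons, and each grey bar the central 95% of 10000 random lists of the same size and mean expression. Red points lie above and blue points below the grey bar, as for histone genes in the first panel at 1.78, and dark points lie within it. Lists with fewer than 5 measured members have no point.

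**Figure D3:**
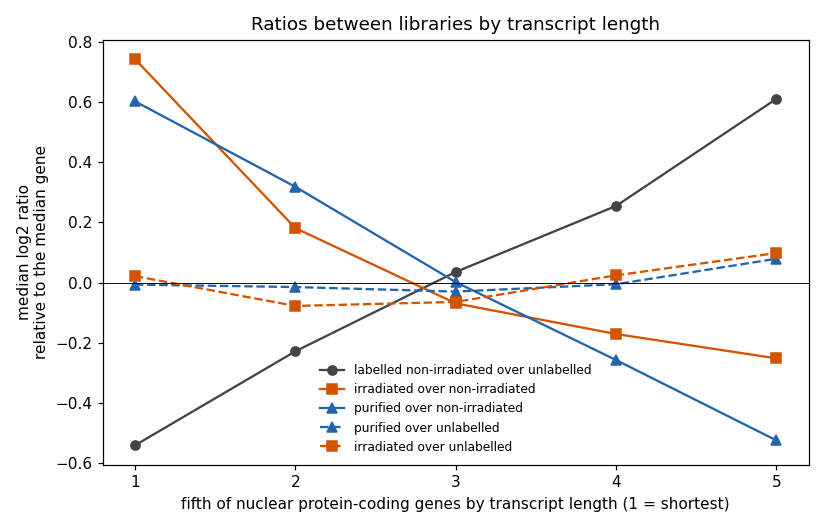
Points give the median log2 ratio, relative to the median gene, in 5 equal bins of nuclear protein-coding genes with a mean FPKM of at least 5, ordered by transcript length. Ratios that have the labelled non-irradiated library on either side follow length (from -0.54 to 0.61 for labelling, from 0.74 to -0.25 for irradiation and from 0.60 to -0.52 for purification), whereas those of the purified and irradiated libraries over the unlabelled one stay between -0.08 and 0.10.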

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

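Under the alternatives chosen before the data were examined, 149 of 183 calls of lists that stood apart were kept, 23 ended and 11 changed sign, and in 11 other cases a list newly stood apart, leaving out centring, which cannot move values taken relative to the median gene. Under alternatives chosen after seeing the data (rescaling over protein-coding genes, length or GC matching, the purified library as the labelled one), 63 of 90 were kept, 21 ended and 6 changed sign, and in 13 other cases a list newly stood apart. Counts of entries at least 2-fold apart depended on scaling and pseudocount, and beyond those constructions the cause was not tested. With a pseudocount of 5 they were 792 higher and 2761 lower for labelling, 95 and 6755 for irradiation, and 1055 and 331 for purification. With a mean FPKM of at least 5, which leaves fewer entries, they were 863 higher for labelling, 5363 lower for irradiation and 352 lower for purification. Centring gave 3497 higher and 2268 lower for labelling and 2099 and 1788 for irradiation. Rescaling without mitochondrial, rRNA and small RNA entries gave 638 higher and 11493 lower for labelling, 19 higher for irradiation, and 6587 higher and 290 lower for purification. Unnamed IDs absent from the reference annotation stayed in that sum. Rescaling over nuclear protein-coding genes gave 3274 higher and 1504 lower for labelling, 293 higher for irradiation, and 329 higher and 1941 lower for purification. With the unlabelled library as reference 280 were higher for irradiation and 3585 lower for purification, and with the irradiated library as reference 12127 were higher and 241 lower for purification.

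By gene ID, 17 lists could be matched on length, without histone, mitochondrially encoded and non-coding RNA genes. Of the 7 among them that stood apart for purification, 3 still did with length-matched random lists and 4 with length and GC matching, and 4 and 5 of the 17 stood apart in all. For labelling 5 of 9 still did with either, and 7 of the 17 stood apart with length matching; for irradiation 4 of 7 still did with either, and 6 of the 17 stood apart. Histone genes, paired by gene name, stayed apart in all 3 comparisons. The distance of a list median from its random lists (log2) changed sign as follows. With the unlabelled library as reference, for irradiation it was 0.34 for KRAB zinc finger, -0.14 for mitochondrial ribosomal protein, -0.0084 for interferon-stimulated and -0.074 for secreted and membrane glycoprotein genes, and for purification -0.18 for oxidative phosphorylation, 1.87 for small RNA and -0.13 for proteasome genes. With the irradiated library as reference, for purification it was -0.64 for oxidative phosphorylation, -0.47 for histone and 0.73 for splicing factor genes. With the purified library as the labelled one it was 0.47 for mitochondrial ribosomal protein and -0.16 for splicing factor genes. Mitochondrial ribosomal protein genes had 0.042 for labelling and -0.084 for irradiation with length matching, and 0.016 and -0.13 with length and GC matching. Cytosolic ribosomal protein genes had -0.0096 for irradiation with a mean FPKM of at least 5.

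The percent of entries within 2-fold with a pseudocount of 0.1 was 49.0 for unlabelled and labelled non-irradiated, 59.2 for unlabelled and purified, 4.38 for unlabelled and irradiated, 74.0 for non-irradiated and purified, 10.7 for non-irradiated and irradiated and 7.83 for purified and irradiated. With a mean FPKM of at least 5 it was 54.8 for unlabelled and non-irradiated, 5.47 for unlabelled and irradiated, 78.8 for non-irradiated and purified and 16.8 for non-irradiated and irradiated. The depth of the purified and irradiated libraries is unknown, so counting error of low values there cannot be given. No paired analysis was possible because each group is 1 library.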

Other observations

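Secreted and membrane glycoprotein mRNAs, which are translated at the endoplasmic reticulum, were low in the purified library by either reference, although against the non-irradiated one the list did not stand apart with length matching (percentile 7.29). Against the unlabelled library 21 of 40 such genes lay at least 2-fold below the median gene and 1 at least 2-fold above, with a list median 2.06-fold below (percentile 0). Cytosolic ribosomal protein mRNAs were 1.46-fold below in the same comparison (73 genes, percentile 0), with 12 at least 2-fold below. In the irradiated library, against the unlabelled one, S-phase genes (35 genes, 2.42-fold below, percentile 0.13), stress response genes (26 genes, 2.03-fold below, 0.09), proteasome genes (31 genes, 2.10-fold below, 0.66) and splicing factor genes (32 genes, 2.45-fold below, 0) were low, and small RNAs (18 genes, 18.8-fold above, 100), histone genes (43 genes, 4.95-fold above, 100), ribosomal protein genes (2.61-fold above, 99.9) and KRAB zinc finger genes (107 genes, 1.55-fold above, 100) were high. Of the markers of other cell types, no hepatocyte marker was measured at a mean FPKM of at least 1 in any comparison, and at most 4 immune, 3 squamous and 1 fibroblast markers were. FBLN1, the fibroblast marker, was at 44.0 FPKM in the unlabelled and 13.5 in the labelled non-irradiated library, and EPCAM, from the squamous list, at 66.2 and 11.7.

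In the patterns weighed here, the tests of rRNA share, common dilution, length trends against the unlabelled library, carry-over, unnamed entries and histone genes with lengths paired by gene name were chosen after their results had been seen. Matching of the other lists on length or GC content was added after the main values had been seen, with the outcomes that would count for or against length written down before the matched values were. The lower FPKM of nuclear protein-coding genes in the irradiated library is a pattern that a larger share of rRNA may partly explain. Named cytosolic rRNA summed to 2.05 times the non-irradiated value, with no entry named for the long rRNA of the large subunit. FPKM are scaled by mapped fragments, so this ratio follows the share of fragments from these entries, as far as their mix of lengths held. All entries together summed to 1.83 times, so the percent of the summed FPKM in named rRNA went from 12.1 to 13.6. That percent counts short entries more per fragment and is not a share of fragments. Any ratio above 1 had been set to count in favour, so the test is weak. The 30 highest unnamed entries held 75.6% of the summed FPKM in the irradiated library, and 30 of 30 were at least 16-fold higher in the non-irradiated than in the unlabelled library. They were picked for high values in a labelled library, and 7SK (84.5-fold) and U2 entries (73.8-fold) pass that limit too, so copies of rRNA cannot be told apart from other RNA without a poly(A) tail. Their sequences were not examined. The gap between ribosomal protein and splicing factor genes was 2.99 on the log2 scale (3.08 with a pseudocount of 0.1, 2.65 with 5). A single dilution factor for every gene would give none, but these lists were chosen after being seen on opposite sides of the median gene. The gap is thus no independent test. Nor did either list stand apart from its random lists in every alternative, as given above. An effect of irradiation on the recovery of mRNA stays open, untested, because irradiation and library coincide.

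The relation to transcript length was seen in the ratios that hold the labelled non-irradiated library and not in those without it. Spearman's rho of ratio and length was 0.42 for labelling, -0.38 for irradiation and -0.58 for purification. Against the unlabelled library it was near 0, at 0.030 for the purified and 0.047 for the irradiated library, and for purified over irradiated it was -0.030. The trend may thus belong to the non-irradiated library, and its cause was not tested. With random lists matched on length, which also changed the pool and the expression bins, oxidative phosphorylation genes no longer stood apart for purification (percentile 80.2). A length trend would give this, but the other changes were not tested apart from it. Proteasome genes (percentile 99.8) and mitochondrial ribosomal protein genes (percentile 100) still stood apart. This argues against length as the whole source of their higher values, as far as 5 bins each of expression and length can match the lists. Length differences within a bin were not matched. Proteasome genes were nevertheless not higher against the unlabelled library (-0.13), so a low value in the shared library stays open for them, and no biological explanation was tested.

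The higher KRAB zinc finger and histone mRNAs in the labelled library were not accounted for by transcript length and GC content, since both lists lay at percentile 100 of random lists matched on expression, length and GC content (48 of 49 histone genes had a length, 26 of them by gene ID). For histones, more carry-over of RNA without a poly(A) tail may contribute, as the list of small RNAs also lay at percentile 100. The lists did not move together throughout, however. In the purified over the non-irradiated library, histones lay 1.74-fold above the median gene (percentile 100) and small RNAs 1.68-fold below (percentile 0.01). KRAB zinc finger mRNAs are polyadenylated, and no test here bears on carry-over for them. An effect of the nucleosides on transcription or decay stays open for both and untested, because labelling, purification and library coincide.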
